A study of Mus musculus with 5 samples.

How the data were processed

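Gene expression was measured by RNA sequencing of 5 libraries from cultured DRG sensory neurons, in 4 groups: control with NGF (1 library), and trophic withdrawal for 1 h (1), 3 h (1) and 6 h (2). Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, reads were handled with TopHat2 2.0.10, HTSeq and DESeq2 on mm10. Their order and settings, the annotation, and whether counting used strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

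The deposited table holds whole-number counts per gene for 23420 genes, not normalized, and these raw counts were the input of every test. It also holds normalized counts, a signal made by the authors by dividing each library's counts by 1 size factor; the factors equalled recomputed DESeq2 median-of-ratios values, and these columns served only for that check. The 5 log-transformed columns were not used. Total counts ranged from 22330527 to 28879129, and 3 counts, the floor used here, were 0.102 to 0.136 CPM.

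Genes were kept by edgeR's filterByExpr on the groups (minimum count 10, minimum total 15), which left 14705. Libraries were scaled by TMM, and edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3 was fitted to all 5 libraries. With 1 residual degree of freedom the prior degrees of freedom were infinite, so every gene took the trended spread of the 6 h pair (common coefficient of variation 3.84%). Log2 fold changes have SEs from the quasi-likelihood F statistic. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called. Contrasts were 6 h, 3 h and 1 h against control and 6 h against 1 h; a joint test covered any difference between groups, and a slope per hour was fitted separately. The rule without a test added 0.5 CPM and asked for a log2 ratio of at least 1 in both 6 h libraries and a mean of at least 5 CPM.

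Gene lists were fixed before the data were examined; 33 had a tested member and were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry as alternatives. At 1 h and 3 h, and for some lists at 6 h, a list is described by the percentile of its median among 10000 random lists of the same size, matched in 20 expression bins. Genes named in the text follow a rule fixed before the data were examined. At 6 h it took the 15 largest increases and 10 largest decreases among called genes with a mean of at least 5 CPM and the same sign in both libraries. At 3 h and 1 h it took up to 8 and 5. It added up to 4 members of each list with the largest change at 6 h, and Bbc3, Dusp16, Jun, Atf3, Ddit3, Hrk, Bcl2l11, Egln3, Egr1, Ntrk1, Ngfr, Trp53, Casp3, Casp6, Sarm1 and Nmnat2. Predicted genes, pseudogenes and small RNAs were left out of the ranked parts. It gave 160 genes.

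Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors, no filter on low counts, the legacy quasi-likelihood fit, other time scales, leaving out each 6 h library, 2 CPM added or a mean of at least 1 CPM in the rule without a test, and a slope per hour in the list test. Added after seeing the data were corrections for transcript length and GC content (a loess curve per library, from the mm10 gene annotation in the reference set), 4 times the dispersion, limma-voom, a slope with an estimated correlation in the list test, and leaving out the control, 1 h or 3 h library. The tests were tested on simulated counts for 14705 genes with 200 changed genes. All simulated libraries, the lone ones included, were drawn with the trended spread of the 6 h pair. The false rates below therefore do not check whether the lone libraries vary like that pair. For 6 h against control, 50.0% of genes changed 1.25-fold, 90.0% changed 1.5-fold, 88.0% changed 2-fold and 100% changed 4-fold were called, and 3.53% of calls were false. For 3 h against control 94.0% of those changed 2-fold were called, and for 1 h 88.0%, with 4.49% and 6.10% false. The slope per hour called 60.0% of genes changed 2-fold at 6 h. Intervals and floors cover counting error only. Figures were drawn with matplotlib 3.10.9.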

Results

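RNA was sequenced from dorsal root ganglion (DRG) sensory neurons of ICR mouse embryos at E13.5 (embryonic day). These neurons depend on nerve growth factor (NGF) for survival in culture. They were grown for 36 h and then kept with NGF (control, 1 library) or deprived of trophic support for 1 h (1 library), 3 h (1 library) or 6 h (2 libraries). Per the series' design text, RNA from 7 purifications was pooled for each condition, so a library averages over these purifications. The control was labelled 6 h, so the 1 h and 3 h libraries had no control of their own time. Total counts were 27381038 for the control, 26524693 at 1 h, 22330527 at 3 h, and 27200385 and 28879129 at 6 h. The 6 h libraries differed by more than sampling noise (chi-square per gene 5.10, or 3.63 without Rn45s and Lars2) and so were not the same counts deposited again; they were counted as 2 samples. This does not show separate cultures: the same value was 5.07 (3.79 without these genes) between the control and 1 h and 5.37 (4.70) between the control and 3 h. The labels do not say whether the 6 h libraries came from separate cultures, so the p-values below measure the spread between these 2 libraries, which may be technical. Along the leading principal component, which held 55.5% of the variance, the 6 h libraries lay at 23.0 and 22.8, the 3 h library at -8.86, the control at -17.2 and the 1 h library at -19.7.

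The comparison of 6 h with control asked which transcripts had changed late in withdrawal. Hrk, which encodes a BH3-only activator of apoptosis, rose from 16.0 CPM (counts scaled by the TMM library size) in the control to 95.5 ± 1.67 CPM (SD, n = 2), a log2 fold change of 2.58 ± 0.09 (SE; adjusted p = 1.53e-171, edgeR). Bbc3, which encodes the BH3-only protein PUMA, rose from 14.8 to 41.7 ± 0.282 CPM (SD, n = 2; log2 fold change 1.49 ± 0.10). Jun, a transcription factor of the JNK pathway, rose by 1.41 ± 0.07, and Dusp16, a MAP kinase phosphatase that acts on JNK, by 1.26 ± 0.08. Lrrn3, a leucine-rich repeat membrane protein, fell from 159 to 29.3 ± 2.3 CPM (SD, n = 2; log2 fold change -2.44 ± 0.07). Slc6a1, a GABA transporter, fell from 233 to 52.6 ± 2.14 CPM (SD, n = 2; log2 fold change -2.15 ± 0.06). In the mm10 annotation Hrk lies on chromosome 5, 118164648 to 118189478, plus strand, Bbc3 on chromosome 7, 16308393 to 16318205, plus strand, and Jun on chromosome 4, 95049034 to 95052222, minus strand. Dusp16 lies on chromosome 6, 134715468 to 134792625, minus strand, Lrrn3 on chromosome 12, 41451668 to 41486431, minus strand, and Slc6a1 on chromosome 6, 114282635 to 114317532, plus strand.

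Of 14705 genes tested, 2909 passed an adjusted p of 0.05 at 6 h, 1229 higher and 1680 lower. At least 2-fold changes made up 115 of the higher and 174 of the lower genes. Besides Hrk, Bbc3 and Jun, the genes with the largest increases were Lrrtm2 (1.90), Rspo2 (1.70), Gpr137c (1.59), Mgat4c (1.48), Pik3ip1 (1.44), Ppp1r17 (1.38) and Fam19a4 (1.37). Smaller increases in this set were those of Cntnap4 (1.36), Cdh20 (1.34), Kcnmb2 (1.33), Rapgef6 (1.31) and Zfp874b (1.28). The largest decreases were those of March11 (-2.96), Gcnt4 (-2.79), Lrrn3, Greb1l (-2.44), Areg (-2.30), Epha4 (-2.29), Fst (-2.19), Slc6a1, Hpse (-2.11) and Cnih3 (-2.09). Their SEs ranged from 0.06 for Slc6a1 to 0.19 for Fam19a4. A rule without a test, at least 2-fold in both 6 h libraries, was met by 26 higher and 77 lower genes of 11287 with a mean of at least 5 CPM. Only the 6 h pair gave a spread, with 1 residual degree of freedom, and the lone libraries were assumed to vary like it. The count was 607 with DESeq2, 1520 without the filter on low counts and 848 with 4 times the dispersion, a setting chosen after seeing the data.

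Among 29 genes of ERK and NGF signaling feedback, 16 fell, none rose and 13 did not pass (camera adjusted p = 5.14e-26, 1.05e-31 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537 and fry at 0.148). The alternatives here and for the lists below were DESeq2 size factors, an estimated correlation, fry, no filter on low counts and a slope per hour. The estimated correlation and fry rested on 1 residual degree of freedom, so a call that ended there cannot decide whether a list changed. Spry4, an inhibitor of receptor tyrosine kinase signaling, fell by 2.08 on the log2 scale, Vgf, an NGF-induced neuropeptide precursor, by 1.87, Spred3 by 1.48 and Dusp6, a phosphatase of ERK, by 1.37. Egr1, an immediate early gene, had a value of 0.14 (adjusted p = 0.303), and its log2 ratios to control in the 6 h libraries were 0.33 and -0.09. Among 10 dual specificity MAP kinase phosphatases, 3 rose and 4 fell, and the list did not pass (camera adjusted p = 0.806; median 0.03, mean -0.04). Those that rose were Dusp16, Dusp1 (1.09) and Dusp8 (0.91). Of 22 genes of the JNK and axon injury response, 7 rose, 4 fell and 11 did not pass (camera adjusted p = 0.0168, 0.00971 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537, fry at 0.306, no filter at 0.373 and a slope per hour at 0.178). Atf3, a transcription factor induced by nerve injury, rose by 1.18 ± 0.10 and Smad1 by 0.52, and Gadd45g fell by 0.51.

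Of 26 proapoptotic genes, 6 rose, 3 fell and 17 did not pass (camera adjusted p = 0.000864, 0.000218 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537 and fry at 0.0515). Casp3, the executioner caspase, rose by 0.85 ± 0.07 and Bmf by 0.84, and Egln3, a prolyl hydroxylase, fell by 0.82. Bcl2l11, which encodes BIM, had a value of 0.21 (adjusted p = 0.131) and Casp6 of 0.28 (adjusted p = 0.071). Of 12 antiapoptotic genes, 1 rose and 3 fell, with Bcl2l1, which encodes BCL-XL, at -0.77 ± 0.06 (list camera adjusted p = 0.363). Of 27 p53 targets, 4 rose, 2 fell and 21 did not pass (camera adjusted p = 0.0651; 0.019 to 0.537 over 5 alternatives), and the list passed with a slope per hour (0.0212) and without the filter (0.019). Trp53inp1 rose by 0.82 and Btg2 by 0.75, Plk2 fell by 0.84, and Trp53 itself had a value of -0.10 (adjusted p = 0.396). Of 23 genes of axon degeneration and maintenance, 2 rose and 2 fell (camera adjusted p = 0.341). Among them Pde4d fell by 0.66. Sarm1, an axon degeneration enzyme, had a value of 0.12 (adjusted p = 0.305) and Nmnat2, an axon survival factor, of -0.12 (adjusted p = 0.176). The calls of Bmf, Btg2 and Gadd45g ended with DESeq2.

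Of 25 FOXO targets, 11 rose, 1 fell and 13 did not pass (camera adjusted p = 2.51e-05, 6.78e-06 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537 and fry at 0.0515). Pik3ip1, an inhibitor of PI3 kinase, Klhl24 (1.11) and Txnip (0.60) rose, and Irs2, an insulin receptor substrate, fell by 1.91. Of 25 genes of cholesterol synthesis and uptake, 16 fell and none rose (camera adjusted p = 6.34e-13, 4.63e-13 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537 and fry at 0.0889), including Stard4 (-0.79), Ldlr (-0.60) and Mvd (-0.59). Of 17 genes of the unfolded protein response, 1 rose, 10 fell and 6 did not pass (camera adjusted p = 0.000106, 1.41e-05 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537 and fry at 0.212), with Sdf2l1 at -0.83, Creld2 at -0.53 and Herpud1 at 0.52. Of 26 genes of glycolysis and hypoxia, 9 fell and none rose (camera adjusted p = 0.00126, 0.00193 to 0.769 over 5 alternatives; call ended with an estimated correlation at 0.769 and fry at 0.51), with Slc2a3, a glucose transporter, at -0.63 and Hk2, a hexokinase, at -0.69. The call of Hk2 ended with DESeq2. Of 25 autophagy and lysosome genes, 7 rose, 1 fell and 17 did not pass (camera adjusted p = 0.0061, 0.000591 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537 and fry at 0.0515), with Gabarapl1 at 0.42 and Ulk2 at -0.34.

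Of 29 voltage-gated and potassium channels, 2 rose, 12 fell and 15 did not pass (camera adjusted p = 0.000864, 0.000123 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537), with Kcnb1 at -0.67 and Kcna1 at -0.70. Of 13 mechanoreceptor and proprioceptor genes, 4 fell and none rose (camera adjusted p = 0.0193, 0.00272 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537 and fry at 0.0515), with Spp1 at -0.69 and Maf at -0.42; these 2 calls ended with DESeq2. Of 23 nociceptor and NGF dependent genes, 3 rose and 8 fell (camera adjusted p = 0.102). Ret, a receptor of the GDNF family, fell by 0.48, Prrxl1 by 0.82 and Ngfr, the p75 receptor, by 0.48, and Tlx3 rose by 0.69. Ntrk1, the NGF receptor, had a value of -0.12 (adjusted p = 0.187). Of 30 pan-neuronal genes, 5 rose and 7 fell (camera adjusted p = 0.682; median -0.01, mean 0.02), with Stmn4 at 1.02 and Rbfox3 at -0.46. Of 36 axon guidance genes, 6 rose and 10 fell (camera adjusted p = 0.0883), with Nrp1 at -1.07 and Epha5 at 0.62. Of 27 synaptic vesicle and neuropeptide genes, 7 rose and 9 fell (camera adjusted p = 0.0651), with Scg2 at 0.95 and Syt4 at -0.76.

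Of 20 interferon and inflammatory genes, 10 rose and none fell (camera adjusted p = 0.00161, 0.00011 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537 and fry at 0.0625), among them Cxcl10 (0.57), whose call ended with DESeq2. Of 24 proliferation genes, 9 rose and none fell (camera adjusted p = 0.00113, 9.53e-06 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537 and fry at 0.148), with Mcm7 at 0.34. Of 11 replication dependent histones, 4 rose and none fell (camera adjusted p = 0.0061, 0.00317 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537, fry at 0.189 and no filter at 0.28), with Hist3h2a at 0.58. Of 77 cytosolic ribosomal proteins, 9 rose and 2 fell (camera adjusted p = 0.00277, 6.7e-05 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537, fry at 0.189 and a slope per hour at 0.106), with Rps4x at 0.25. Of 73 nuclear oxidative phosphorylation genes, 5 rose and 1 fell (camera adjusted p = 0.015, 0.000591 to 0.537 over 5 alternatives; call ended with an estimated correlation at 0.537, fry at 0.371 and a slope per hour at 0.184), with Atp5c1 at 0.23. The medians of ribosomal proteins at 1 h, 3 h and 6 h were 0.09, 0.06 and 0.07. Those of oxidative phosphorylation were 0.10, 0.07 and 0.07. All of these share 1 control library. After the correction for transcript length, chosen after seeing the data, the 1 h medians were 0.025 and 0.022. An order in time therefore cannot be read from these medians. Ribosomal protein and histone genes have near-identical copies between which reads can be split, so their values are uncertain. The calls of Mcm7 and Atp5c1 ended with DESeq2. Most interferon and inflammatory genes above their list median at 6 h, 0.38, had a mean under 5 CPM. The median of that list at 1 h was -0.10. Markers of other cells in the culture were measured in the same libraries. Of 21 Schwann and satellite glia markers, 7 rose and 2 fell (camera adjusted p = 0.0671), of 18 fibroblast markers, 4 rose (0.0589), of 11 endothelial and blood markers, 1 rose (0.893; median -0.00, list direction up), and of 14 macrophage markers, none passed (0.792). Their median log2 fold changes were 0.12, 0.06, -0.00 and 0.02.

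The remaining lists did not pass at 6 h in the comparison with control. Of 29 ATF4 targets, 5 rose, among them Ddit3 (0.40), and 9 fell, among them Slc7a5 (-0.45) and Eif4ebp1 (-0.50; list camera adjusted p = 0.163, 0.0186 with a slope per hour, 0.0429 without the filter, and 0.0186 to 0.778 over 5 alternatives). Of 16 heat shock genes, 1 rose and 3 fell (0.341), and of 21 cyclin and E2F genes, 3 rose and 3 fell (0.792; median 0.03, mean -0.01), with Mycn at -0.84 and Myc at -0.75. Of 20 serum response factor targets, 5 rose and 2 fell (0.341), of 22 ubiquitin ligases, 1 rose and 2 fell (0.552), and of 37 proteasome subunits, 1 fell (0.792). Adjusted over the list alone, the counts were 0 higher and 19 lower for ERK and NGF feedback, 7 higher and 3 lower for proapoptotic genes, 8 higher and 5 lower for the JNK list and 14 higher and 1 lower for FOXO targets. They were 0 higher and 18 lower for cholesterol, 1 higher and 11 lower for the unfolded protein response and 3 higher and 16 lower for channels. For the other lists that passed, they were 12 higher and 0 lower for interferon and inflammatory genes, 10 higher and 0 lower for proliferation genes, 4 higher and 0 lower for histones, 7 higher and 1 lower for autophagy. They were 8 higher and 2 lower for ribosomal proteins, 4 higher and 0 lower for oxidative phosphorylation, 0 higher and 10 lower for glycolysis and 0 higher and 4 lower for mechanoreceptor genes. With a preset correlation of 0.01, 15 lists passed. None passed with an estimated correlation, which had 1 residual degree of freedom, and 2 passed with fry, which used the same fit. The smallest unadjusted p with an estimated correlation was 0.0751 (camera, cholesterol list), so no list could pass there after adjustment. With so few degrees of freedom neither test can decide which lists changed.

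**Figure D1:**
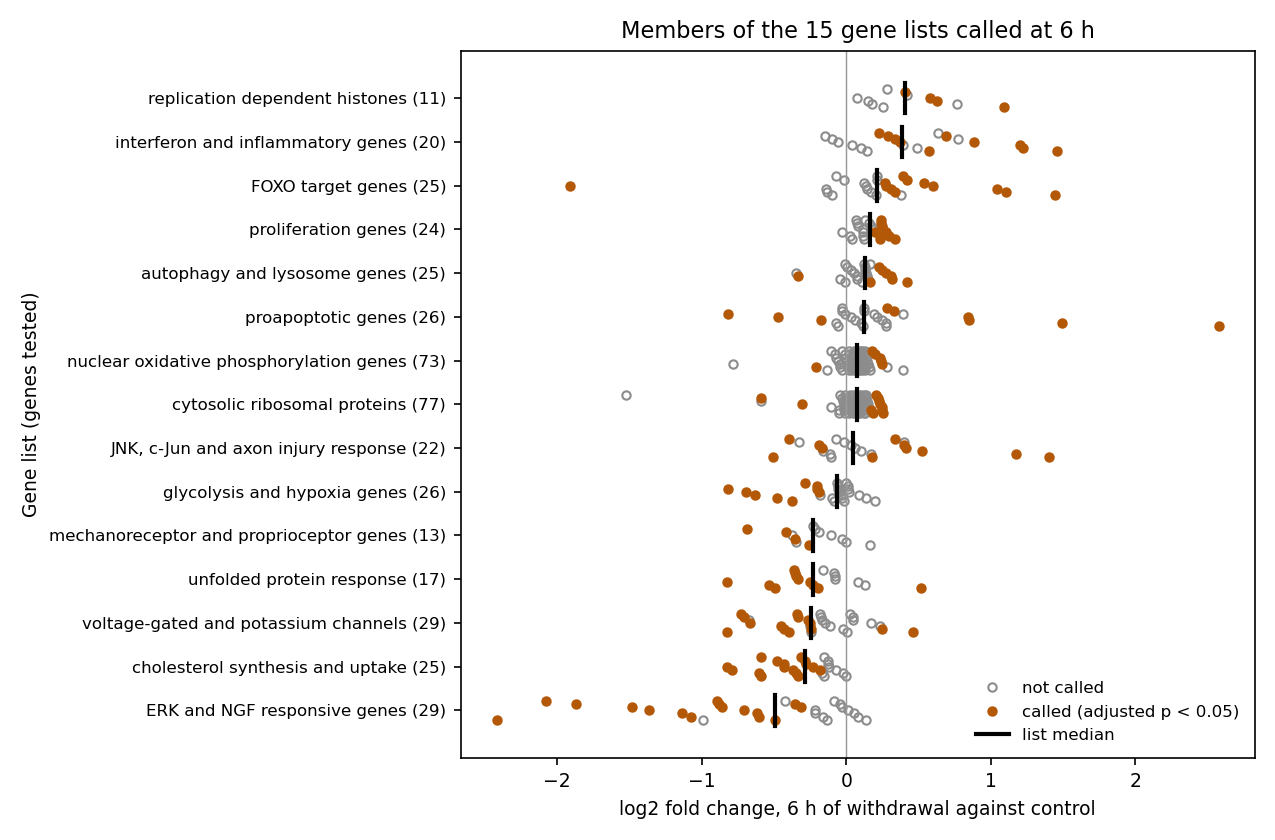
Log2 fold change at 6 h of withdrawal against control (x axis) of each member of the 15 lists called by camera (y axis, with the number of genes tested). Filled points are genes with an adjusted p under 0.05, open points are the others, and black bars are list medians; the ERK and NGF list has the lowest median, -0.49, and replication dependent histones the highest, 0.41.

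The 3 h library was compared with the control to find earlier changes. Jun had already risen by 1.28 ± 0.08 (SE; adjusted p = 7.17e-52, edgeR), from 53.5 to 130 CPM. Dusp1 (0.99), Tlx3 (0.98), Isl2 (0.95), Gpr137c (0.93), AI593442 (0.85), Dusp8 (0.83) and Sh2d3c (0.81) were also higher. Spry4 fell by 1.79, Areg by 1.78, Gcnt4 by 1.58, Irs2 by 1.43 and Id2, an inhibitor of DNA binding, by 1.41. Bbc3 (0.71), Dusp16 (0.62) and Hrk (0.61) were higher too, and each rose further by 6 h (6 h against 3 h, adjusted p at most 8.65e-13, edgeR), while Casp3 had a value of 0.13 (adjusted p = 0.807). Of the 29 ERK and NGF feedback genes 7 had fallen, and their median of -0.13 lay at percentile 0 of 10000 random lists matched on expression. The median of the interferon and inflammatory list, 0.43, lay at percentile 100, with 3 of 20 genes higher. In all 187 genes passed, 68 higher and 119 lower. With 1 library on each side the comparison has no replicate check of its own. The count was 36 with DESeq2, 42 without the filter on low counts and 56 with 4 times the dispersion.

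Genes called at 3 h were looked up at 6 h. Of the 68 higher genes 54 were also higher at 6 h and of the 119 lower genes 113 were also lower, against 5.68 and 13.6 for independent lists. Both comparisons share the control library. Simulated libraries with no effect gave a correlation of fold changes across genes of 0.564, and the observed value was 0.555; the covariance was 0.0216 observed and 0.00662 simulated. A single control cannot be divided, so part of the overlap may come from it. In the comparison of 6 h with 1 h, which shares no library with 3 h against control, 50 of the 68 and 108 of the 119 passed in the same direction.

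The 1 h library was compared with the control to find the earliest changes. It held 21 called genes, 7 higher and 14 lower. Lars2, a mitochondrial leucyl-tRNA synthetase, had a log2 fold change of -1.05 ± 0.07 (SE), and Nova1 (-0.96), Igsf9b (-0.65), Onecut2 (-0.48) and Xist (-0.46) were lower as well. Pam16 was higher by 0.47 ± 0.12 (SE; adjusted p = 0.0497, edgeR). Jun had a value of 0.22 (adjusted p = 0.515) and Hrk of 0.01 (adjusted p = 0.995). Among the 33 lists, the medians of ribosomal proteins (0.09) and oxidative phosphorylation (0.10) lay at percentile 100 of 10000 random lists matched on expression, and those of FOXO targets (-0.13), axon guidance (-0.09) and channels (-0.12) at percentile 0. Fold changes at 1 h fell with transcript length (Spearman -0.45 across 11237 genes), and these random lists were not matched on length. After a correction for length, chosen after seeing the data, these medians were, in the same order, 0.02 (percentile 95.1), 0.02 (percentile 93), -0.10 (percentile 0), -0.06 (percentile 0.02) and -0.04 (percentile 1.6). The glycolysis list then lay at percentile 0. Of the markers of other cells, fibroblast lay at 99.96, Schwann at 99.62, endothelial at 0.01 and macrophage at 14.07. Lars2 differed within the 6 h pair too, whose SD was 274 CPM around a mean of 531. The SE of 0.07 for Lars2 at 1 h rests on the spread trended over all genes and understates this variation. Of the 14 lower genes 13 had an annotated transcript, with a median length of 15455 bases, against 3432 for all tested genes with one. DESeq2 called 0 genes and edgeR without the filter 0, while 953 had an unadjusted p under 0.05 in edgeR. After a correction for transcript length 2 genes were called, after one for GC content 7, with 4 times the dispersion 6 and with limma-voom 10, all settings chosen after seeing the data.

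**Figure D2:**
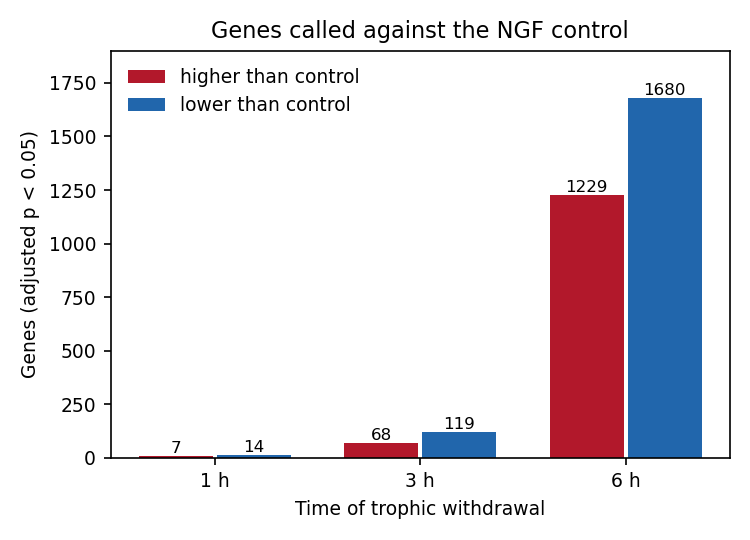
Number of genes with an adjusted p under 0.05 in edgeR (y axis) at 1 h, 3 h and 6 h of withdrawal against the control (x axis), higher in red and lower in blue. The counts rise from 7 and 14 at 1 h to 1229 and 1680 at 6 h, where 2 libraries rather than 1 were compared.

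The time course as a whole asked how changes were ordered in time. Jun, Spry4 and Dusp6 had made most of their change by 3 h, with log2 fold changes at 3 h and 6 h of 1.28 and 1.41, -1.79 and -2.08, and -1.29 and -1.37. Of these, Spry4 still differed between 3 h and 6 h (adjusted p = 0.00504, edgeR). Vgf and Slc6a1 stood at -0.13 and -0.25 at 3 h and at -1.87 and -2.15 at 6 h. Chac1, a glutathione-degrading enzyme, was lower at 3 h (-0.51) and higher at 6 h (0.39), the latter not with DESeq2. A test for any difference between the 4 groups called 3733 genes, of which 1303 had their largest change at 6 h as an increase and 1772 as a decrease. Their largest change was at 3 h for 125 higher and 118 lower genes and at 1 h for 154 and 261. This sorts genes by their largest fold change and does not test the change at that time. Most genes sorted to 1 h were not called in the comparison of 1 h with control. That comparison rests on 1 library, and its fold changes fell with transcript length (Spearman -0.45). A straight line over hours, with 3 residual degrees of freedom, called 2768 genes, 1208 rising and 1560 falling. Between 6 h and 1 h, 3529 genes differed, 1572 higher and 1957 lower at 6 h. The time course count was 730 with DESeq2, 1394 without the filter and 1003 with 4 times the dispersion, and the 6 h against 1 h count 766, 2077 and 1018. The line called 1009 genes over the order of the times, 1179 and 1248 without 6 h replicates 1 and 2, and 1614 without the 1 h library.

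**Figure D3:**
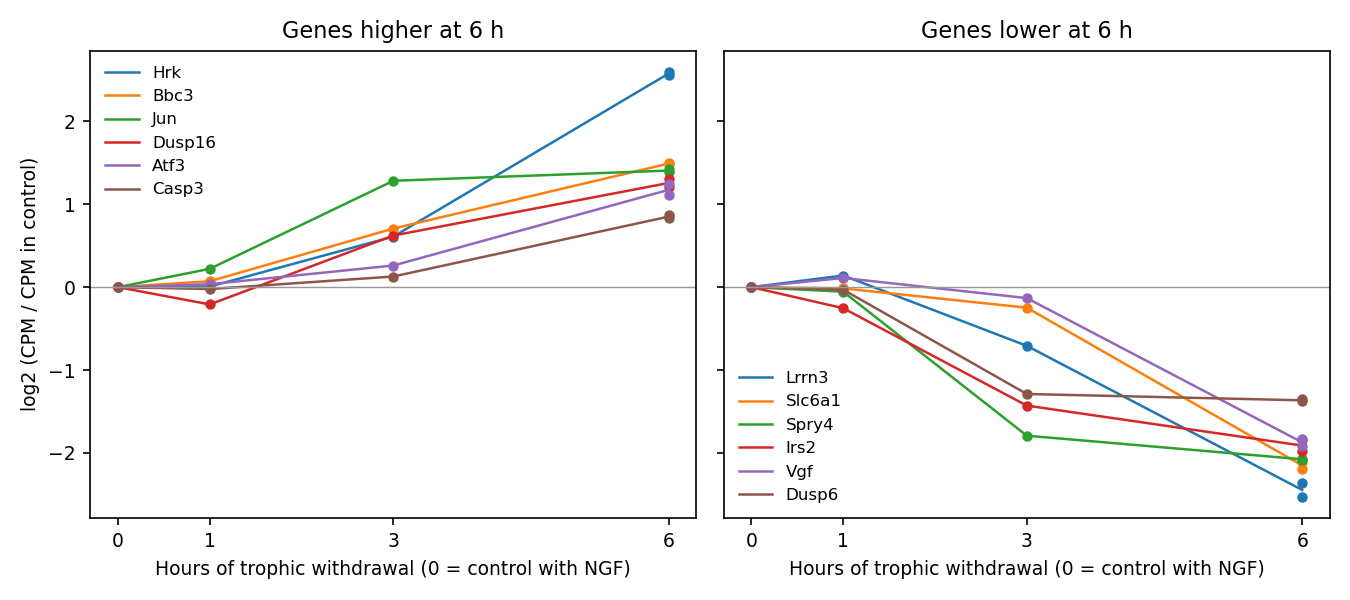
Log2 ratio of CPM to the control library (y axis) against hours of withdrawal (x axis) for 6 genes higher and 6 genes lower at 6 h; points are libraries and lines join the mean of each time. Jun, Spry4 and Dusp6 change mostly by 3 h, while Hrk, Vgf and Slc6a1 change mostly between 3 h and 6 h.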

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

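The effects at 6 h and at 1 h against the same control were compared by the test of 6 h against 1 h (edgeR, adjusted p under 0.05), and they differed for 124 of the 160 named genes, 63 higher and 61 lower at 6 h. Most named genes were chosen for a large change at 6 h or 1 h, so this share does not describe other genes; of all 14705 tested genes 3529 differed. Values in parentheses are the log2 effect at 6 h minus that at 1 h. Higher at 6 h were Hrk (2.57), Rspo2 (1.98), Ppp1r17 (1.93), Lrrtm2 (1.86), Cntnap4 (1.66), Mgat4c (1.66), Fam19a4 (1.59), Pik3ip1 (1.57), Gpr137c (1.55), Rapgef6 (1.53), Dusp16 (1.47), Kcnmb2 (1.44), Bbc3 (1.42), Zfp874b (1.31), Klhl24 (1.26), Jun (1.19). Then came Isl2 (1.17), Cdh20 (1.15), Atf3 (1.14), Bmf (1.09), Scg2 (1.06), AI593442 (1.05), Trp53inp1 (1.02), Stmn4 (0.98), Lars2 (0.98), Dusp8 (0.88), Casp3 (0.87), Cxcl10 (0.86), Txnip (0.84), Sh2d3c (0.80), Dusp1 (0.74), Tlx3 (0.73). Next were Hist1h1c (0.68), Epha5 (0.65), Ifit2 (0.64), Smad1 (0.58), Foxo3 (0.55), Rb1 (0.55), Filip1l (0.54), Chac1 (0.53), Btg2 (0.53), Nova1 (0.52), Herpud1 (0.51), Hist3h2a (0.50), Ddit3 (0.41), Xist (0.39), Syn2 (0.37), Cdh19 (0.36). The smallest positive differences were Hbb-y (0.35), Hist3h2ba (0.34), Bcl2l11 (0.34), Map1lc3b (0.33), Kif11 (0.30), Gabarapl1 (0.29), Aurka (0.29), Birc2 (0.27), Sarm1 (0.24), Rps15a (0.21), Mcm7 (0.21), Hsp90aa1 (0.21), Cox7a2 (0.20), Mdm2 (0.20), Rps4x (0.17). Lower at 6 h, from the smallest difference, were Nmnat2 (-0.18), Psmd3 (-0.19), Maf (-0.23), Ndufs7 (-0.24), Psmd12 (-0.25), Nedd4l (-0.26), Bcl2 (-0.29), Rps4y2 (-0.29), Pam16 (-0.29), Siah2 (-0.30), Srf (-0.31), Etv1 (-0.31), Ulk2 (-0.32), Spp1 (-0.33), E2f3 (-0.38), Rbfox3 (-0.40). Larger decreases followed for Dnajb1 (-0.40), Slc2a3 (-0.46), Ret (-0.46), Ngfr (-0.48), Slc7a5 (-0.49), Eif4ebp1 (-0.49), Creld2 (-0.49), Hk2 (-0.49), Hsd17b7 (-0.50), Pvalb (-0.53), Manf (-0.56), Kcnb1 (-0.56), Mvd (-0.58), Pde4d (-0.60), Kcnd3 (-0.61), Ldlr (-0.63). Further decreases were Kcna1 (-0.67), Egln3 (-0.68), Myc (-0.72), Kcnc4 (-0.73), Stard4 (-0.77), Plk2 (-0.79), Syt4 (-0.80), Pcsk1 (-0.80), Prrxl1 (-0.82), Bcl2l1 (-0.83), Mycn (-0.85), Sdf2l1 (-0.97), Nrp1 (-1.01), Dusp6 (-1.33), Spred3 (-1.50), Irs2 (-1.65). The largest were Vgf (-1.98), Id2 (-2.002), Spry4 (-2.02), Cnih3 (-2.10), Slc6a1 (-2.13), Hpse (-2.22), Epha4 (-2.29), Greb1l (-2.33), Areg (-2.43), Fst (-2.46), Lrrn3 (-2.58), Gcnt4 (-2.90), March11 (-3.13). With only 6 h replicate 1 or only replicate 2, the difference moved by over 1.5 times for Lars2 (0.33 and 1.43), Map1lc3b (0.22 and 0.43), Cox7a2 (0.11 and 0.30) and Rps4y2 (-0.46 and -0.13).

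The tests in this and the next paragraphs were chosen after the results were seen, except those on liver and muscle genes not yet looked at. Of the 14 genes called lower at 1 h, the 13 with an annotated transcript had a median length of 15455 bases, and Spearman's correlation of fold change with length across 11237 genes, which are not independent, was -0.45 at 1 h, -0.20 at 3 h and -0.02 at 6 h. Across the 11237 genes, the -0.20 at 3 h, less than 0.5 times that at 1 h, argues against a length trend that builds up with time of withdrawal. The 14 genes themselves had median log2 fold changes of -0.07 at 3 h and -0.20 at 6 h. They were picked for low values at 1 h and all times share 1 control library. These medians therefore cannot decide whether an effect on the 14 genes lasted. After a correction for length, 0 of the 14 were still called. Their median log2 fold change went from -0.43 (bootstrap SE over genes 0.13) to -0.27 (0.15). The median shift per gene was 0.16 (bootstrap SE 0.02). The curve was fitted to the length trend of these same libraries and these genes are long, so a shift towards 0 was built in. The shift cannot tell what made the trend, and a difference between libraries that follows length stays possible. After a correction for GC content 4 were still called, but the median was -0.42 (bootstrap SE 0.13) and the median shift per gene -0.0049 (0.0054), while the median SE of single genes went from 0.08 to 0.09; the calls ended without a shift of the folds towards 0, and the test leaves GC open. A requirement that the folds shift towards 0 by over 2 bootstrap SEs was added after both results were seen. Spearman's correlation of fold change with GC content was 0.10 at 1 h, 0.27 at 3 h and -0.24 at 6 h, so a trend with GC content was not limited to 1 h. Between the 6 h libraries the correlation was -0.01 with GC content and 0.10 with length. An effect of withdrawal on the 14 genes, brief or lasting, stays open and untested, since there is 1 library at 1 h.

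Rn45s, the ribosomal RNA precursor, took 0.306% of counts in the control (exact 95% binomial interval 0.304 to 0.309), 0.145% at 1 h, 0.179% at 3 h, and 0.164% and 0.340% at 6 h. The log2 ratio of Lars2 to control followed that of Rn45s within 0.26 in all 4 withdrawal libraries, while the median of 16 other mitochondrial tRNA synthetases stayed within 0.07 of 0, which is consistent with a different amount of ribosomal RNA left in each library. An effect of withdrawal on these transcripts stays open. It would be argued against if the 6 h libraries differed from each other by at least as much as 1 h from control. They differed by 1.05 in Rn45s, under the 1.07 at 1 h, and by 1.11 in Lars2, over the 1.05 at 1 h. Both margins (-0.03 and 0.05) lie within the SE of the 1 h values (0.08 and 0.07). These SEs come from the spread trended over all genes, not from that of Rn45s and Lars2, so they cannot decide the margins. The 1 h differences were about as large as those between the 2 libraries of 6 h.

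Transcripts of other tissues differed between libraries. Of 5 liver genes looked at first, 4 were highest at 3 h, with Alb and Afp at 4.66 CPM against at most 0.07 CPM elsewhere. Ambp and Serpina6 were at 0.724 and 0.860 CPM at 3 h and had no counts elsewhere. Ttr was at 4.08 CPM at 1 h, 0.860 at 3 h and 0.587 in the control. Of 21 other detected liver genes 57.1% were highest at 3 h, between the bounds of 75% and 50% set before the test. The test on these 21 genes therefore neither supports nor argues against liver tissue in this pool. With 1 library at 3 h, a response of the neurons cannot be told apart from liver tissue. Of these 21, only Trf and Vtn were at over 30 CPM in every library. Of 7 muscle genes looked at first, 5 were highest at 1 h, 1 at 3 h and 1 at 6 h. Myh3 was at 0.184 CPM in the control, 3.32 at 1 h, 0.452 at 3 h, and 1.13 and 2.18 at 6 h, and Actc1 at 0.294, 3.20, 0.452, 0.727 and 2.01 CPM. Of 22 other detected muscle genes 20 (90.9%) were higher at 1 h than in the control, 9 at 3 h, and 11 and 18 in the 6 h libraries, so the pattern was not of the 1 h library alone. Their summed level differed within the 6 h pair (1.22-fold, at percentile 99.0 of 10000 random lists matched on expression, a comparison chosen after the result was seen). This goes with a different share of muscle tissue in each pool if the 6 h libraries are separate pools and against it if they share 1 pool, which the labels do not say, so this explanation stays open, as does an untested effect of withdrawal at 1 h. Myh3, Actc1 and Myog, named after their values were seen, were 3 of the 7 higher calls at 1 h.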

How the results depend on the processing

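Settings other than DESeq2, DESeq2 size factors, no filter, the legacy fit, time scale, left-out 6 h libraries, the pseudocount and minimum of the rule without a test, and the list tests other than a slope with an estimated correlation were chosen after seeing the data. No paired analysis was possible because the labels give replicate numbers only at 6 h. DESeq2 size factors and the legacy fit kept every count of called genes within 1.5 times. With DESeq2 the counts were 607 (6 h), 36 (3 h), 0 (1 h), 766 (6 h against 1 h) and 730 (time course), and 2092 for the line. Without the filter on low counts they were 1520, 42, 0, 2077 and 1394. With 4 times the dispersion they were 848, 56, 6, 1018 and 1003. At 1 h limma-voom called 10, the length correction 2 and the GC correction 7. At 3 h the length correction called 132 and the GC correction 144. At 6 h they called 2617 and 2524, of which 2593 and 2302 were among the main calls. The line called 1009 genes over the order of the times, 1179 to 1248 without either 6 h library and 1614 without the 1 h library, and 2927 without the control. The rule without a test gave 103 genes, 83 with 2 CPM added, 141 with a mean of at least 1 CPM, 104 with DESeq2 size factors, and 117 to 118 without either 6 h library. Of the lists, 15 passed; 0 passed with an estimated correlation, 0 with a slope and an estimated correlation, 2 with fry, 16 with DESeq2 size factors, 14 with a slope per hour and 17 without the filter. Of the 15, 12 also passed with the slope, without JNK, ribosomal proteins and oxidative phosphorylation, and 13 without the filter, without JNK and histones. Lists gained were p53 and ATF4 targets with both, Schwann and fibroblast markers without the filter, synaptic genes with DESeq2 size factors and axon guidance with fry. Fry and the estimated correlation on the groups had 1 residual degree of freedom, so they cannot decide which lists changed. Of the 160 named genes 132 were called at 6 h; 54 of these calls ended with DESeq2 and 25 without the filter, and none of the 160 changed sign with DESeq2, with its size factors or without the filter. Without 6 h replicate 1 the values of Egr1 and Lars2 changed sign, and without replicate 2 that of C1qc, none of them called. In these settings 1 and 13 of the 160 values moved by over the SD of the pair. Each 6 h library lies within about that SD of the pair's mean whatever the gene, so these counts do not measure stability. Apart from the fewer libraries in the left-out settings, the cause was not tested. Leaving out a 6 h library ends the group tests, since no residual degree of freedom remains.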

Other observations

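The tests here were chosen after the results were seen, except that on p53 targets. The p53 list was tested again without Bbc3 and gave a camera p of 0.197 (limma, 1 test, not adjusted), so a rise of p53 targets beyond Bbc3 was neither shown nor excluded. Of the genes called at 3 h, 90.9% had the same sign in 6 h against 1 h, which shares no library with that comparison; this is consistent with changes that start by 3 h and persist. The medians of the 4 lists of non-neuronal markers at 6 h differed by up to 0.12, over 2 bootstrap SEs. The pair compared was the highest and the lowest of the 4, which passes this bound more easily than a preset pair. The test therefore leaves open whether a lower share of neurons raised all of them alike.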
